A study of Mus musculus with 12 samples.

How the data were processed

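Total RNA of sorted bone marrow myeloma cells from 6 mouse lines was turned into heavy and light chain libraries with molecular identifiers, per the labels' protocols. The genome build is mm10, per the submitters' processing notes. For each of the 12 libraries the deposited clone table gives a count per clonotype, as whole numbers. Whether a count is a read or a molecule is not given in the sources used here. The deposited clone tables also give the fraction of each clonotype, which equals its count over the sum of the table. Some clone numbers are skipped while the fractions still sum to 1, so clonotypes may have been removed before deposit in 4 tables, which was not tested. The skipped numbers are 3 in the VQ-D1 light, 3 in the VQ-D2 light, 2 in the VQ-D5 heavy and 1 in the VQ-D5 light chain table. The column names and hit format are those that MiXCR exports, per the file headers, and the version and filters are not given in the sources used here. For the heavy chain a second deposited table gives 1 aligned sequence per molecular identifier group with AIRR columns as IgBLAST writes them, and the V identity to the germline allele in percent, per the file headers. Its version and germline set are not given in the sources used here.

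The VQ-D2 light chain table ends in 2 lines that name no clonotype, 1 blank and 1 sum, and these were left out. All else was used as deposited. A clonotype was a V gene, a J gene and a CDR3 base sequence. The share of the largest clonotype was taken over all clonotypes of the library, with exact Clopper-Pearson 95% intervals. Because amplified copies are not independent molecules, intervals and limits cover counting error only. A count of 0 was given the limit of 3 counts. The effective number of clonotypes was the exponential of the Shannon entropy. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

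Groups were taken from the labels: 4 primary donor lines and 2 lines derived from VQ-D2. Nothing in the labels says that 4935 and 4938 are independent of each other. Derived and primary lines were compared by exact permutation of the difference of means over 15 splits, and heavy and light chains over 924 splits, all two-sided. Benjamini-Hochberg adjustment covered these 5 tests. Heavy and light chain libraries of a number come from the same line, per the labels, so the pairing is by line. The paired form was an exact sign-flip test over 64 sign choices, which left the comparison on the same side of the threshold. No batch is given in the labels. These tests, the alternatives and the rule for naming clonotypes were fixed before the data were examined. The rule named the largest clonotype of each library, any other with at least 5% of a library, the clonotypes shared by several lines (the 5 largest per chain) and constant genes with at least 1% of a library. The substitutions listed, IGHD segments and any other clonotype named in the closing part were chosen after their values were seen.

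V identity used distinct sequences with at least 200 aligned V bases. Clone sequences were assigned by V gene, because most lack a CDR3. A fixed substitution was one present in at least 50% of the distinct sequences covering a position, with at least 5 sequences and with 10 bases left out at each alignment end. These 3 settings were chosen after the sequences had been seen. Libraries with fewer than 20 clone sequences of 200 V bases, 4935 and 4938, used sequences with at least 50 V bases. That limit of 20 sequences was first 5 and was raised after the values of 4938 were seen. At the earlier limit 4938 gave 6 substitutions from 8 sequences, a V identity of 97.4% and 3 of 6 in WRC/GYW (two-sided exact binomial p = 0.023). The caller was tested on simulated data: of 160 substitutions planted in a VQ-D2 V segment, 160 were recovered with 0 false calls, at 8, 266 and 400 sequences. Each was planted in every simulated sequence, below V position 200, and false ends were shorter than the 10 bases left out. Full recovery was thus nearly built in. Substitutions in part of the sequences, later V positions and the short alignments of 4935 and 4938 were not tested. Gene coordinates came from the RefSeq gene table of the same build, where 20 of 20 genes looked up were matched by name.

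Several points departed from the plan. Constant genes were taken from the clone tables, since the aligned tables hold no constant gene call. Variants within the clone were counted in a window from V position 80 to 180 rather than over full-length sequences, in 1000 draws of 265 sequences, and the window was chosen after coverage was seen. 4935 and 4938 had too few sequences with a long V alignment for that measure. The comparison with other clonotypes used sequences of other V genes, which VQ-D5 alone had, by exact permutation over 8 splits. Merging CDR3 ends, the motif check of isotypes, the pooled hotspot test, the paired test without VQ-D1, the tests on primary lines alone, the heavy chain shares of aligned sequences set against light chain clone tables and the choice of 3 of 6 lines were added after the data were seen. Kappa sequences in heavy chain libraries were those with a constant kappa motif, assigned to a V gene by at least 100 shared stretches of 20 bases, a limit set after the numbers per sequence were seen. Earlier forms of this assignment, where they gave values, also placed no VQ-D4 sequence and 1 VQ-D5 sequence in IGKV3-12. An earlier form of the test for false joins searched only the bases just before the CDR3 and found no inverted V segment, after which the test and its stated expectation were rewritten to use the strand of the V alignment. The share with V bases on the same strand was first taken over all sequences and then over those that lack the CDR3 start and have a V alignment. The test of carry-over first used a bound that no library here was deep enough to reach, and was replaced by the ratio of other kappas to IGKV3-12. Fisher's exact tests of kappa counts between libraries were also computed and are not reported, because the counts cannot be taken as independent molecules. Sequences that look unlike mouse were not reported, and clonotypes with 1 count had no sequence printed. No genome sequence was used.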

Results

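B cell receptor transcripts were sequenced from CD138-positive, B220-negative bone marrow myeloma cells of the mouse VQ model. These cells carry a MYC transgene under kappa light chain control elements, an activated Nras allele and a Cre recombinase expressed with IgG1. The 12 libraries covered 6 lines, with 1 heavy chain and 1 light chain library per line. VQ-D1, VQ-D2, VQ-D4 and VQ-D5 were the 4 primary donor lines, and 4935 and 4938 were 2 cell lines derived from VQ-D2. Clonotype counts summed to between 1277 and 4602 per primary heavy chain library and between 1618 and 3584 per primary light chain library. The derived lines were shallower, with 411 heavy and 385 light chain counts in 4935 and 373 and 212 in 4938. With 1 library per line and chain there were no replicates within a line, so shares of single libraries have exact Clopper-Pearson 95% intervals that cover counting error only. Spreads between lines are SDs.

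A single rearranged heavy chain held nearly all counts of the clone table in 5 of the 6 heavy chain libraries. VQ-D2 carried an IGHV4-1/IGHD1-1/IGHJ1 rearrangement with the CDR3 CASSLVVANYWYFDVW, which took 100% of 2568 counts (interval 99.9% to 100%). VQ-D4 carried IGHV7-3/IGHD2-4/IGHJ4 with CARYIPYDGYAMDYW at 100% of 1277 counts (99.7% to 100%). VQ-D5 carried IGHV3-8/IGHD1-1/IGHJ1 with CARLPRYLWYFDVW at 99.5% of 2181 counts (99.2% to 99.8%), but at only 36.3% of the 6124 aligned sequences with a CDR3, where a second CDR3 had 1563 sequences against its 2221. The 36.3% counts each of 475 exact CDR3s apart. Of the 21572 aligned VQ-D5 sequences with at least 200 V bases, 21561 were assigned to IGHV3-8 or a V gene tied with it. What gave the second CDR3 was not tested. VQ-D1 carried IGHV3-1/IGHD2-4/IGHJ2 with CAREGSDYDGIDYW at only 57.5% of 4602 counts (56.1% to 58.9%). The other 42.5% of VQ-D1 (41.1% to 43.9%) was an out-of-frame clonotype assigned to IGHV3-2, whose 35 CDR3 bases equal the last 35 of the 42 bases of the first. The 4 largest clonotypes of the primary lines were in frame and used 4 different V genes. Over the 4 primary lines the largest heavy chain clonotype took 89.3% ± 21.2 (SD, n = 4) of counts, and with in-frame clonotypes alone VQ-D1 reached 100%. The V assignment of VQ-D1 is uncertain, because the aligned sequences of the same library were assigned to IGHV3-2 rather than IGHV3-1.

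All of these genes lie on chromosome 12 in mm10. IGHV4-1 spans 113948284 to 113948577, IGHV3-1 spans 113964390 to 113964683, IGHV3-2 spans 114033803 to 114034097, IGHV7-3 spans 114153180 to 114153644 and IGHV3-8 spans 114322376 to 114322666. IGHJ1 spans 113429781 to 113429833, IGHJ2 spans 113429468 to 113429515 and IGHJ4 spans 113428514 to 113428567. The RefSeq table annotates IGHV3-2 and IGHV7-3 as V segment pseudogenes, although the IGHV7-3 clonotype of VQ-D4 was in frame.

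**Figure D1:**
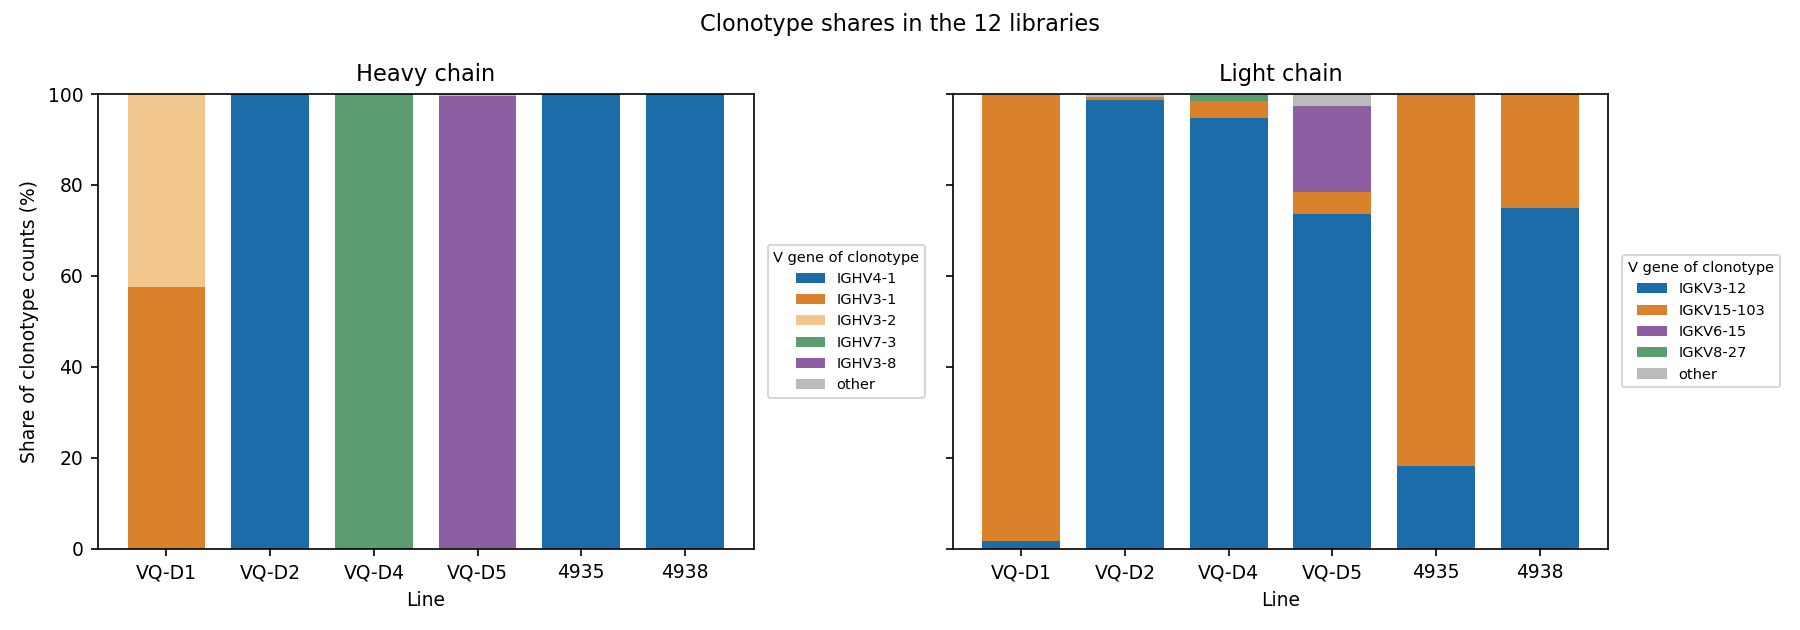
Share of clonotype counts (percent, bars starting at 0) in the 6 heavy chain libraries (left) and the 6 light chain libraries (right), coloured by the V gene of the clonotype, with small clonotypes grouped as other. VQ-D1 is split between 57.5% and 42.5% in the heavy chain, and IGKV3-12 and IGKV15-103 are present in all 6 light chain libraries.

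The light chain libraries were led by 1 of 2 kappa rearrangements. IGKV3-12/IGKJ5 with the CDR3 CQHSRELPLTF was the largest clonotype in VQ-D2 at 98.7% of 1748 counts (98.0% to 99.2%), in VQ-D4 at 94.7% of 1618 (93.5% to 95.7%), in VQ-D5 at 73.5% of 2223 (71.7% to 75.4%) and in 4938 at 75% of 212 (68.6% to 80.7%). IGKV15-103/IGKJ1 with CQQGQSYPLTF was the largest in VQ-D1 at 98.1% of 3584 counts (97.6% to 98.5%) and in 4935 at 81.6% of 385 (77.3% to 85.3%). VQ-D5 also held an IGKV6-15/IGKJ2 clonotype with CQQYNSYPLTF at 18.8% (17.2% to 20.5%). Over the 4 primary lines the largest light chain clonotype took 91.3% ± 11.9 (SD, n = 4) of counts. On chromosome 6 of mm10, IGKV3-12 spans 70518250 to 70518849, IGKV15-103 spans 68437468 to 68437925 and IGKV6-15 spans 70406469 to 70406992. Part of the IGKV3-12 signal of VQ-D4 and VQ-D5 is open to doubt, since 0 of 22 assigned kappa sequences in the VQ-D4 heavy chain library and 1 of 10 in that of VQ-D5 were IGKV3-12.

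The derived lines were compared with the primary lines for how far 1 clonotype dominates. Both derived lines held a single heavy chain clonotype, the IGHV4-1 rearrangement of VQ-D2, at 100% (SD 0, n = 2) against 89.3% ± 21.2 (SD, n = 4) in the primary lines. Their largest light chain clonotype, IGKV15-103 in 4935 and IGKV3-12 in 4938, took 78.3% ± 4.64 (SD, n = 2) against 91.3% ± 11.9 (SD, n = 4). IGKV15-103 took only 0.686% in VQ-D2, where IGKV3-12 took 98.7%, although 4935 carried the VQ-D2 heavy chain clonotype. The derived mean thus joins 2 different kappas and may not measure dominance of the clone. The effective number of clonotypes, the exponential of the Shannon entropy, was 1 in both derived heavy chain libraries against 1.25 ± 0.482 (SD, n = 4). In the light chain it was 1.69 ± 0.0847 (SD, n = 2) against 1.46 ± 0.605 (SD, n = 4). None of these 4 differences passed a two-sided exact permutation test: share +10.7 points in the heavy chain (p = 0.733) and -13.0 points in the light chain (p = 0.4), and effective number -0.254 (p = 0.733) and 0.235 (p = 0.733). All Benjamini-Hochberg adjusted values over 5 comparisons were 0.733. The smallest p that 15 splits of 6 lines allow is 0.0667, and 4935 and 4938 are not independent of VQ-D2. The heavy chain difference rests on VQ-D1, without which it was 0.153 points.

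Heavy and light chains of the same lines were compared as measures of clonality. In VQ-D4 and VQ-D5 the largest light chain clonotype, IGKV3-12, may not be the kappa of the clone. It was 0 of 22 and 1 of 10 assigned kappa sequences in their heavy chain libraries. 4935 was led by another kappa than its donor VQ-D2. Light chain shares may therefore not measure clonality in these lines. In the clone tables the largest heavy chain clonotype took the greater share in 5 of 6 lines, by 1.32 points in VQ-D2, 5.32 in VQ-D4, 18.4 in 4935, 25 in 4938 and 26.0 in VQ-D5. In VQ-D1 the IGHV3-1 clonotype stood at -40.6 points relative to IGKV15-103. The means were 92.8% ± 17.3 for heavy and 86.9% ± 11.6 for light chains (SD, n = 6 each). The difference of 5.91 points did not pass a two-sided exact permutation test over 924 splits (p = 0.426, adjusted 0.733). Without VQ-D1 the difference was 15.2 points (exact permutation p = 0.00794), but pairing the chains by line, a test added later, gave an exact p of 0.0625, the smallest that 5 pairs allow. VQ-D2, 4935 and 4938 share 1 clone and are not independent, and over the 4 primary lines alone the difference was -2.003 points (exact permutation p = 1). Merging clonotypes by shared CDR3 ends joins the IGHV3-2 clonotypes of VQ-D1 and of VQ-D5 (2 counts) to the largest clonotype of their library. The difference was then 8.65 points over the primary lines (exact permutation p = 0.0286, paired 0.125) and 13.0 over all 6 lines (exact permutation p = 0.00216, paired 0.0312). With heavy chain shares from the aligned sequences it was -8.09 points (exact permutation p = 0.522, paired 0.312), with the heavy chain higher in 2 of 6 lines. That setting changes the heavy chain side alone, counts each exact CDR3 apart (475 in VQ-D5 against 10 clonotypes) and rests on 12 sequences in 4935 and 33 in VQ-D4, so it is no like-for-like comparison of the chains.

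Sharing of clonotypes between lines was examined for the relation of 4935 and 4938 to their donor. The IGHV4-1 clonotype of VQ-D2 was the largest in all 3 of the related libraries, so 3 of 3 related pairs had the same largest heavy chain clonotype against 0 of 12 unrelated pairs. It was not detected in VQ-D4 (0 of 1277 counts, which allows up to 0.235%), and it had 1 count in VQ-D5 (0.0459%, interval 0.00116% to 0.255%). VQ-D1 had 0 counts of it, which sets no limit, because this clonotype is IGHA and the VQ-D1 library held IGHG2B alone, so the 5 pairs of VQ-D1 with other lines say little about heavy chain sharing. The IGHV4-1 clonotype was the only 1 of 13 heavy chain clonotypes found in more than 1 line. Among the 20 choices of 3 of the 6 lines, only the related 3 shared their largest heavy chain clonotype (one-sided exact p = 0.05, the smallest possible), a test that counts VQ-D1 as not sharing.

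Sharing of kappa clonotypes could not show this relation, because every pair of lines shared at least 1. IGKV3-12 and IGKV15-103 were found in all 6 lines, and all 12 unrelated pairs shared a kappa clonotype, as did 3 of 3 related pairs. The largest kappa clonotype was the same in 1 of 3 related and 6 of 12 unrelated pairs. IGKV3-12 took 1.65% in VQ-D1 (1.26% to 2.12%) and stood at 18.2% in 4935 (14.5% to 22.4%). IGKV15-103 took 0.686% in VQ-D2 (0.355% to 1.20%), 3.83% in VQ-D4 (2.95% to 4.89%), 4.95% in VQ-D5 (4.08% to 5.93%) and 25% in 4938 (19.3% to 31.4%). The other shared kappas named here were IGKV6-15, with 418 counts in VQ-D5, 3 in VQ-D1 and 1 in VQ-D2, and IGKV8-27/IGKJ1 with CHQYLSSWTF, with 24 counts in VQ-D4 (1.48%) and 1 in VQ-D2. IGKV12-89/IGKJ1 with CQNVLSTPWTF had 2 counts in VQ-D5 and 1 in VQ-D2. In total 6 of 40 light chain clonotypes were found in more than 1 line. IGKV15-103 to IGKV3-12 counts were 314 to 70 in 4935 and 53 to 159 in 4938.

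Each heavy chain library held transcripts of a single constant gene. All counts of VQ-D1 were IGHG2B (100%, interval 99.9% to 100%), an IgG subclass. All counts of VQ-D2, VQ-D4, VQ-D5, 4935 and 4938 were IGHA, the IgA heavy chain, with lower interval bounds between 99.0% and 99.9%. IGHM and IGHD, the constant genes of B cells before class switching, had 0 counts in every library, as did IGHG1, IGHG2A/C, IGHG3 and IGHE. For a class that was primed, a count of 0 allows up to 0.0652% in VQ-D1 and up to 0.804% in 4938. In mm10, IGHA spans 113256204 to 113260236 and IGHG2B spans 113304314 to 113307933 on chromosome 12. The primers used per library are not given in the sources used here, so classes that were not primed would also give 0 counts.

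Heavy chain V segments of VQ-D1, VQ-D2 and VQ-D5 carried fixed base substitutions, while none was found in VQ-D4. The IGHV4-1 clonotype of VQ-D2 had 8 substitutions in at least 50% of the distinct sequences covering each of 273 positions (2.93%, interval 1.27% to 5.69%). Counted from 1 at the 5′ end of the germline V allele, they were C20T, G104A, A135T, C170A, A174C, A227G, G251C and T278A, of which 6 replaced an amino acid. The IGHV3-8 clonotype of VQ-D5 had 6 (2.20%, 0.811% to 4.72%), which were A116T, A142T, G147T, C156G, C260T and G264C, with 5 replacements. VQ-D1 had 5 (1.82%, 0.595% to 4.21%) against IGHV3-2, which were G36T, C63A, G176A, G234A and A284T, with 2 replacements. The IGHV7-3 clonotype of VQ-D4 had 0 over 284 positions, where the limit of 3 counts is 1.06%. Every covered position was called, so this limit and the intervals treat positions as if they were draws. Of the 284 positions, 193 were covered by at least 100 sequences. In 4935 all 6 covered VQ-D2 substitutions were present, from 11 sequences, and in 4938 all 7 covered, from 71 sequences. Neither derived line had a further substitution of this kind at the positions it covered, which were 151 in 4935 and 233 in 4938. Positions outside these were not examined. A germline difference of the mouse strain from the reference allele would be counted as a substitution. The VQ-D1 positions may also be differences between IGHV3-1 and IGHV3-2, since its in-frame clonotype was counted under IGHV3-1.

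**Figure D2:**
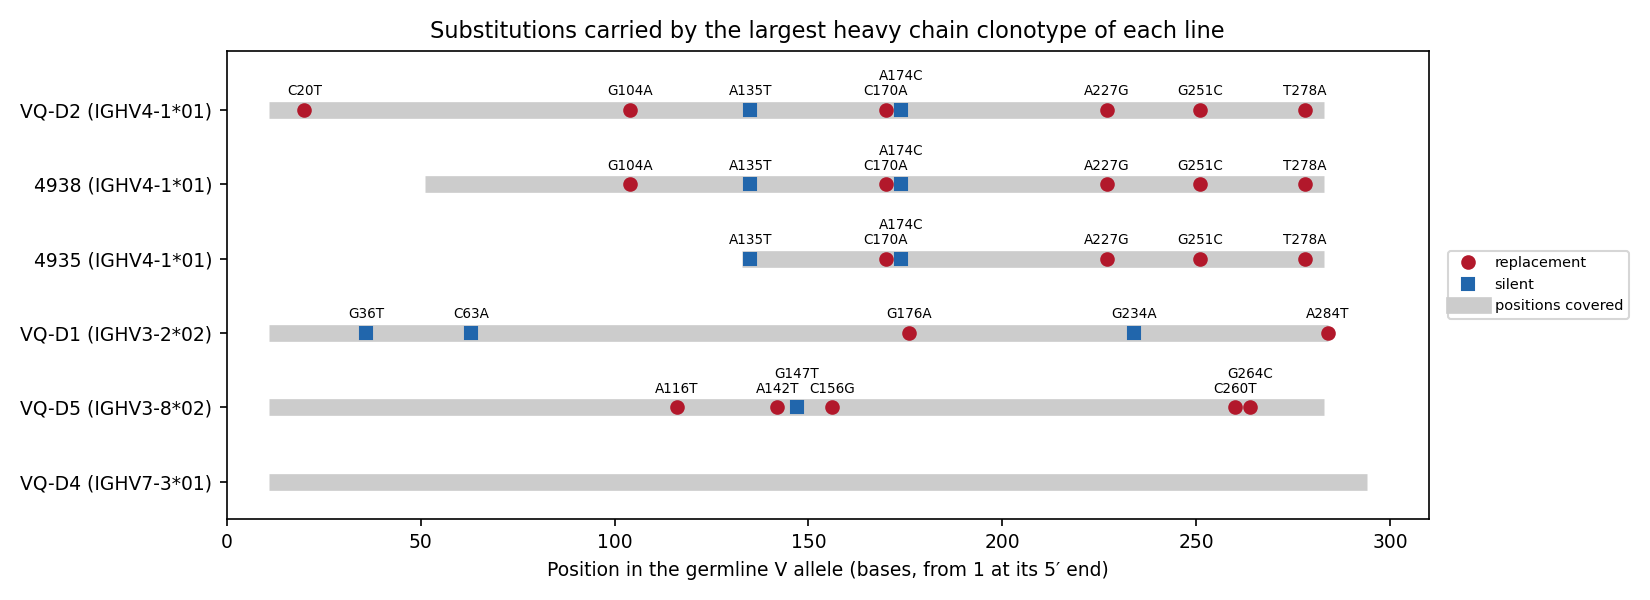
Position along the germline V allele (bases, from 1 at its 5′ end) of the substitutions in at least 50% of the covering distinct sequences of each line's largest heavy chain clonotype, with red circles for replacement, blue squares for silent changes and grey bars for covered positions. 4938 and 4935 carry the 7 and 6 VQ-D2 substitutions that they cover, and VQ-D4 carries none.

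The mean V identity to germline, taken over distinct sequences of at least 200 V bases, was 97.0% in VQ-D1 (2625 sequences), 95.8% in VQ-D2 (17760), 97.8% in VQ-D4 (250) and 96.2% in VQ-D5 (16743). The mean of these 4 lines was 96.7% ± 0.914 (SD, n = 4). It was 95.02% in 4938 from 8 sequences and 86.5% in 4935 from 1 sequence. Because the clone was assigned by V gene, other CDR3s with that V gene counted as the clone. Only VQ-D5 had sequences of other V genes, which were 11 sequences of 7 V genes with a mean over V genes of 98.1%. They include 3 IGHV4-1 sequences (mean 96.0%) that carried 16 of the 17 VQ-D2 substitutions they covered, so this set is not only the background of VQ-D5. IGHV3-8 stood at -1.91 points relative to them, which did not pass a two-sided exact permutation test (p = 0.5, smallest possible 0.125). These identities are not free of sequencing errors or of alignment ends, and the VQ-D4 value is 100% when only substitutions in at least 50% of sequences count.

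The positions of the substitutions were compared with WRC/GYW motifs, the preferred targets of the deaminase AID. Counted in any sequence, as fixed before the data were examined, 93.2% of V positions of VQ-D1, 98.0% of VQ-D2 and 97.6% of VQ-D5 were mutated, so the comparison had little room to differ in these lines. The mutated share was 63.5% in VQ-D4 and 15.02% in 4938. The motif share of mutated positions was 13.5% in VQ-D1 (p = 0.649), 11.8% in VQ-D2 (p = 0.854), 13.5% in VQ-D4 (p = 0.747), 12.2% in VQ-D5 (p = 0.855) and 18.2% in 4938 (p = 0.161), by two-sided exact binomial tests. With positions mutated in at least 50% of the sequences, an alternative fixed before the data were examined, the IGHV4-1 clonotype of VQ-D2 had 4 of 8 in such motifs against 11.6% of V positions (exact p = 0.00862). That set keeps the alignment ends, and of the 8 substitutions listed for VQ-D2, from which the ends are left out, 3 lay in such motifs (G104A, C170A and G251C; exact p = 0.0445). The IGHV3-8 clonotype of VQ-D5 had 3 of 6 against 11.9% (exact p = 0.0258) and that of VQ-D1 had 2 of 5 against 12.6% (exact p = 0.122). Pooled over these 3 donors with alignment ends left out, a test added later, 8 of 19 positions lay in WRC/GYW (42.1%) against 10.7% of the V positions (two-sided exact binomial p = 0.000445). The same pooled counts were 1 of 19 for SYC/GRS coldspots (exact p = 0.717) and 6 of 19 for WA/TW motifs of polymerase eta (exact p = 0.263). These p-values are unadjusted. The 5 VQ-D1 positions in the pooled counts were called against IGHV3-2 and may be germline differences from IGHV3-1, to which its clonotype was assigned.

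Sequence variants within each clone were counted over V positions 80 to 180, in draws of 265 sequences. The median number of distinct sequences was 63 in VQ-D1, 102 in VQ-D2, 136 in VQ-D4 and 101 in VQ-D5. The mean pairwise differences were 1.79, 2.56, 3.83 and 2.69 bases in these lines. Neither measure is free of sequencing errors, so neither ranks the clones by diversification. With sequences seen once in the whole library left out, the mean pairwise differences were 0.763 in VQ-D1, 0.694 in VQ-D2, 0.639 in VQ-D4 and 0.589 in VQ-D5. These last values rest on 2412, 20274, 148 and 16754 sequences, and being seen once depends on depth, so they do not rank the lines. In VQ-D1 the substitution A80G, at the first position of this window, was in 1029 of 2432 distinct sequences covering it (42.3%). It can add to the VQ-D1 values, but how much was not computed, and what gave it was not tested. The partial substitutions listed for VQ-D2, VQ-D4 and VQ-D5 lay after V position 180. The most frequent of them was G188T in VQ-D4, at 14%. 4935 and 4938 had 1 and 5 sequences over this window, too few for a value. No test was made between lines, with 1 library each.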

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

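All tests of explanations in this part were chosen after the results were seen, and those on joins, on kappa sequences and on carry-over were reworked after first outputs. A library was singled out when its gap to the nearest of the 4 primary lines was large relative to their range. Of 11 such groups, 5 had a library of this kind, where chance gives about 1 in 20 groups. Several of these measures are related, so they are not 5 separate events.

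VQ-D1 stood apart in the heavy chain, with 57.5% in its largest clonotype and an effective number of 1.98. Its IGHV3-2 clonotype may be a product of falsely joined paired reads. Of 1128 aligned sequences that lack the CDR3 start, 1022 (90.6%, interval 88.7% to 92.2%) had the V segment on the opposite strand. Of these 1128, 1023 had a V alignment. Among 3993 sequences with the full start and a V alignment, 18.5% had the V segment on the opposite strand. Sequences that lack the start were 20.1% of 5621 aligned ones while the clonotype held 42.5% of the clone table counts. What sets this gap was not tested. A subclone with the 7 bases TGTGCAA deleted is argued against, since 1 of the 1023 sequences that lack the start and have a V alignment had V bases of the same strand there (upper bound 0.543%). A second rearrangement, the other biological explanation tested, is argued against by the 35 bases that equal the end of the first CDR3.

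Kappa sequences in the heavy chain libraries lay outside the main measurement and above the limit that a count of 0 allows in VQ-D4, at 7.02% of 342 sequences (interval 4.55% to 10.3%), and in VQ-D5, at 0.0434% of 23019 (0.0208% to 0.0799%). Of the assigned ones, 22 of 22 in VQ-D4 were IGKV8-27, only 1 of them with a whole CDR3 and the others by V sequence alone, and 9 of 10 in VQ-D5 were IGKV6-15, all 9 with a whole CDR3. If they are independent molecules, the upper bounds for IGKV3-12 of 15.4% and 44.5%, against 94.7% and 73.5% in the light chain libraries, argue against IGKV3-12 being the kappa of those cells at its light chain library share, and the VQ-D2 heavy chain clonotype, whose exact 95% interval reached at most 0.288% in both lines (VQ-D4, where the limit of 3 counts is 0.235%), argues against admixed VQ-D2 cells as the whole source of IGKV3-12, though not against a trace. Carry-over of the VQ-D5 light chain library would bring IGKV6-15 to 24.2% in VQ-D4, where its exact 95% interval reached 0.228% (limit of 3 counts 0.185%). Carry-over of the VQ-D4 library would bring IGKV8-27 to 1.15% in VQ-D5, where its exact interval reached 0.166% (limit of 3 counts 0.135%). Exchange between these 2 libraries is thus argued against as the whole source of IGKV3-12. Carry-over of the VQ-D2 library cannot be told apart from a kappa sequence that all lines share, such as one in the transgene, because beside IGKV3-12 and IGKV15-103 VQ-D2 held no kappa of at least 2 counts to trace it (its 1-count clonotypes, 0.629% of counts, were not used), and no transgene sequence was used here.

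VQ-D5 had 10 heavy chain clonotypes against 1 or 2 in the other primary lines, but 8 of them had 1 count each, and the 2 left without these equal the number in VQ-D1. The largest light chain share of VQ-D5 was 73.5%, below the other primary lines. The light chain effective number of VQ-D5 was 2.36, above the other primary lines.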

How the results depend on the processing

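Merging CDR3 ends, the motif check of isotypes, the values with 10 bases trimmed at alignment ends, the paired test without VQ-D1, the tests on primary lines alone and the heavy minus light difference from aligned sequences were chosen after the data were seen. Of 202 alternatives over 42 results, 161 stayed on the same side or within the spread, 26 moved and 4 reversed. Another 11 newly passed the threshold and 0 no longer passed, as no main result had. Where no reason is named, the cause was not tested. The largest heavy chain share of VQ-D1 became 100% with productive clonotypes alone or CDR3 ends merged. From the aligned sequences it was 88.5% in VQ-D1, 89.5% in VQ-D2, 87.9% in VQ-D4, 36.3% in VQ-D5, 83.3% in 4935 and 87.5% in 4938. Without 1-count clonotypes VQ-D5 heavy was 99.9% and VQ-D2 light 99.3%. At 2 counts in both libraries, 0 unrelated pairs shared a heavy chain clonotype. Leaving out each line in turn, derived minus primary ranged from 0.153 to 14.3 points for heavy and -18.9 to -9.70 for light shares, and from -0.339 to -0.0133 and 0.115 to 0.536 for heavy and light effective numbers. The values nearest 0 in the heavy chain were those without VQ-D1, and the light effective number was highest without VQ-D5 and lowest without VQ-D2. None could pass the threshold in designs this small. Heavy minus light ranged from 1.89 points without VQ-D5 to 15.2 without VQ-D1, with 2.09 without 4938 and 3.40 without 4935. With the replicate block, which pairs the chains of a line, it was 5.91 points (exact p = 0.531). With CDR3 ends merged it was 13.0 points (exact permutation p = 0.00216) and with the block p = 0.0312, each the smallest possible, so the call changes with this merging. It moved VQ-D1 heavy from 57.5% to 100% and VQ-D5 heavy from 99.5% to 99.6%. Without VQ-D1 the block gave p = 0.0625, by the exact sign-flip test. Over the 4 primary lines alone the difference reversed to -2.003 points (exact p = 1 with and without the block). With CDR3 ends merged as well it was 8.65 points (exact permutation p = 0.0286, with the block 0.125). With heavy chain shares from aligned sequences it reversed to -8.09 points (exact permutation p = 0.522, with the block 0.312), but only the heavy chain side changes table there.

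V identity with productive sequences alone was 98.2% in VQ-D1, 98.9% in VQ-D4 and 93.8% in 4938. From fixed substitutions it was 98.2% in VQ-D1, 97.1% in VQ-D2, 100% in VQ-D4, 97.8% in VQ-D5, 96.0% in 4935 and 97.0% in 4938. It leaves out substitutions in under 50% of sequences and alignment ends together, and lowers the minimum to 50 V bases in 4935 and 4938. With no minimum alone 4935 was already 95.03%, and with 250 V bases 4938 was 91.4%, from only 2 sequences. The WRC/GYW share at positions mutated in at least 50% of sequences was 50% in VQ-D2, VQ-D5 and 4938. With ends trimmed it was 37.5% (exact p = 0.0445), 50% (0.0187) and 42.9% (0.0344), against 2 of 5 in VQ-D1 (exact p = 0.0957) and 2 of 6 in 4935 (exact p = 0.14). 4935 and 4938 share their substitutions with VQ-D2 and add no separate support. Counted in any sequence, the WRCY/RGYW share passed in 4938 alone, at 13.6% or 6 of 44 (exact p = 0.0405). Pairwise differences without sequences seen once were 0.763, 0.694, 0.639 and 0.589 in VQ-D1, VQ-D2, VQ-D4 and VQ-D5. Long V alignments limit 4935 and 4938 most: 12 of 294 and 72 of 826 aligned sequences had 50 V bases, against 277 of 342 in VQ-D4, and 1 and 8 had 200. Depth limits light chain shares most in 4938, with 212 counts.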

Other observations

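The test of the isotype primer below was chosen after the result was seen. The smaller clonotypes of VQ-D5 included a group of 4 related kappas with IGKV12-46/IGKJ1. They held 30 counts, or 1.35% of 2223 (interval 0.912% to 1.92%), and their lowest CDR3 base qualities ranged from 22 to 32. The second heavy chain clonotype of VQ-D5, assigned to IGHV3-2 with 2 counts, also had an out-of-frame CDR3 of 35 bases, which is the end of the 42 bases of its IGHV3-8 clonotype. In the aligned sequences of VQ-D5, with each exact CDR3 counted apart, 2221 of 6124 sequences with a CDR3 had that of the IGHV3-8 clonotype. The second most frequent one had 1563, and what gave it was not tested.

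VQ-D5 also held 3 aligned sequences of IGHV4-1, the V gene of VQ-D2. They carried 16 of the 17 VQ-D2 substitutions that they covered.

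The single constant gene per heavy chain library may come from 1 isotype primer per reaction. Among 1890 products that held no sequence of the clone, 1356 carried a constant region sequence taken as the primer of the library's own class and 0 carried that of the other class, which allows up to 0.221%, while 534 carried neither. Both sequences were read from product ends of these same libraries, so matches to the library's own class are partly built in, and only the absence of the other class bears on the hypothesis. The primers themselves are not given in the sources used here.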
